A study of Homo sapiens with 6 samples.

How the data were processed

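The data were RNA-seq gene tables of MM1S, a human multiple myeloma cell line, with 3 libraries from cells carrying a non-targeting CRISPR guide (control) and 3 from TRAF2 knockout cells (TRAF2 KO). Per the labels' protocols, cells grew in RPMI medium with serum and without treatment, total RNA was extracted with an RNeasy kit, and libraries were made from 1 µg of RNA with an NEBNext Ultra RNA kit, which the labels do not describe as strand-specific. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. The titles name 1 guide per genotype, guide number 1 for the control and guide number 2 for TRAF2, so any effect of the guide or of the expanded cell population cannot be separated from the genotype. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

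Reads were aligned with STAR and quantified with RSEM, with DESeq2 and the build hg19 also listed, per the submitters' processing notes, and no versions were given in the sources used here. Each deposited file held, per the file headers, 1 library's expected count per gene, which RSEM estimates by sharing ambiguous reads between genes and which need not be whole. The deposited TPM column held abundances scaled by the authors to the same sum in each library. The deposited files also held the standard deviation of each count over RSEM's sampling and an abundance-weighted transcript length per gene. The gene identifiers were versioned Ensembl identifiers paired with symbols, of a release not stated. Because the stated build differs from that of the reference annotation used here, no coordinates are printed, and the reference served only for chromosome and gene order, with 99.5% of the tested genes matched by identifier.

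Expected counts were rounded to whole numbers. Of the 60656 genes in the files, 13345 passed edgeR's filterByExpr and were tested, and they held over 99% of the counts of each library. Main tests were edgeR's quasi-likelihood F tests with TMM factors and robust dispersions (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM are counts scaled to the TMM-adjusted library total, given as mean ± SD with n = 3 libraries per group unless stated. Log2 fold changes are TRAF2 KO over control. Their standard errors (SE) are approximate, namely the absolute log2 fold change divided by the square root of the quasi-likelihood F. For a large fold from few control counts this SE is too small and can lie below counting error alone. For a gene with 0 counts in all libraries of a group, the fold is a lower bound against 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio is given with a 95% exact binomial counting interval.

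Before the data were examined, 28 gene lists were fixed, along with the main test, the alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 28 lists, and again with a correlation estimated from the data. In addition, fry was run, which asks whether a list's genes moved on balance one way and does not compare them with other genes. The naming rule took 20 genes of the TRAF, NF-kB, ERK and cereblon pathways, the 7 largest rises and 7 largest falls among genes past the test with a mean of at least 5 CPM, a gene name and no overlap between groups, and the 3 members of each list with the smallest adjusted p. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule or a test takes in are not reported here.

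The test was run on counts simulated for the 13345 genes from the means, dispersions and library sizes of the TRAF2 KO and control samples, of which 13119 passed the filter. It recovered 54% of 50 genes changed 1.25-fold and 64% of 50 changed 1.5-fold. Of 50 changed 2-fold and 50 changed 4-fold it recovered 86% and 94%, and it called 9 of 13145 unchanged genes. Genes that missed the filter counted as not recovered. Far fewer genes were changed there than passed the test in the data, which makes the adjustment stricter, so these shares may understate recovery. In a second simulation of 13117 genes, camera called the 1 planted list and 0 of 27 random lists, but simulated genes vary independently, which genes of a real list need not do.

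Within groups, the counts of library pairs differed beyond sampling noise, with a chi-square per gene of 2.86 to 5.35, so no library was treated as a repeat of another. The alternatives were RLE, upper quartile and library-total scaling, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, limma trend on log2(TPM + 1) and on log2(TPM + 0.1), the replicate number as a block, non-robust dispersions, and leaving out each library in turn. The lists were not run with DESeq2 or log2(TPM + 0.1), and camera with an estimated correlation was a further alternative for them, which makes 16. The intervals and floors given cover counting error only.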

Results

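Gene expression was measured by RNA-seq in MM1S cells, a human multiple myeloma line, in 3 control libraries with a non-targeting guide and 3 TRAF2 KO libraries. The series concerns ERK signalling and resistance to immunomodulatory drugs, which act through cereblon (CRBN). The comparison asks how the transcriptome of untreated cells differs once TRAF2 is knocked out. TRAF2 is an adaptor that brings the ubiquitin ligases BIRC2 and BIRC3 (cIAP1 and cIAP2) to TRAF3 and the kinase NIK (MAP3K14), which holds non-canonical NF-kB signalling down. Library totals ran from 16855679 to 19202670 expected counts. At these depths 3 counts in 1 library corresponded to 0.156 to 0.178 CPM, and means near or below this rest on few counts. The 10 most abundant genes took 5.83% to 6.47% of the counts and mitochondrial genes 1.65% to 2.10%.

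TRAF2 (ENSG00000127191.18, on chromosome 9) was at 45.2, 48.5 and 46.4 CPM in the 3 control libraries and at 32.7, 36.8 and 37.9 CPM in the 3 TRAF2 KO libraries. Its mRNA fell by 0.38 on the log2 scale (SE 0.07, edgeR adjusted p = 1.9e-05) and thus stayed at 76.6% of the control mean. A guide-directed edit changes the coding sequence and need not remove the transcript, so this level does not measure TRAF2 protein. Of 13345 tested genes, 4863 passed the edgeR test, 2469 higher and 2394 lower in TRAF2 KO. At least 2-fold changes were found for 855 genes, 540 higher and 315 lower, and at least 4-fold changes for 219 higher and 63 lower genes. In 6106 genes (45.8%) the groups did not overlap, where chance gives 10%. The first principal component held 67.7% of the variance and separated the genotypes. Pearson's r across genes, which are not independent replicates, was 0.989 to 0.990 within groups and 0.962 to 0.963 between groups. With 1 guide per genotype, differences between the 2 cell populations that arose apart from TRAF2 are part of these counts.

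**Figure D1:**
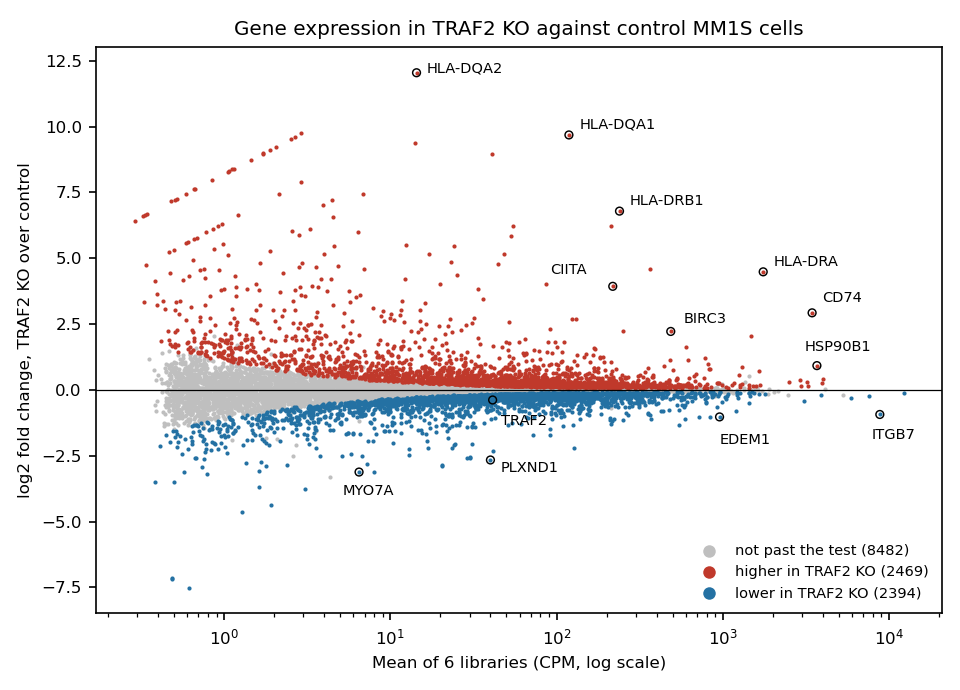
Each point is 1 of the 13345 tested genes, with the mean CPM of the 6 libraries (log scale) against the log2 fold change of TRAF2 KO over control, and red and blue mark the 2469 higher and 2394 lower genes past the edgeR test. The labelled HLA class II genes lie far above 0 and TRAF2 close to it, and the heights of genes with no counts in a group, such as HLA-DQA2, depend on the prior count.

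HLA class II genes, which present peptides from the endocytic route to CD4 T cells, had the highest median log2 fold change of the 28 lists. CD74, the invariant chain, went from 803 ± 31 (SD, n = 3) to 6104 ± 48 CPM (SD, n = 3), a log2 fold change of 2.93 (SE 0.03, edgeR adjusted p = 2.0e-39). HLA-DPA1 rose from 29.3 ± 1.7 to 699 ± 20 CPM, HLA-DPB1 from 5.56 ± 0.43 to 421 ± 5.8 CPM and HLA-DRB1 from 4.28 ± 0.23 to 474 ± 13 CPM. The log2 fold changes of HLA-DPA1, HLA-DPB1 and HLA-DRB1 were 4.58, 6.24 and 6.79, from 1663, 316 and 243 counts over the control libraries. Their SE are not given, since the approximate SE is too small at such folds. HLA-DQA1 went from 0.279 ± 0.213 (16 counts, most of them in control replicate 3) to 237 ± 6.5 CPM. HLA-DQB1 went from 0.157 ± 0.104 (9 counts) to 82.1 ± 3.9 CPM. HLA-DOA had 2 counts over the control libraries, both in control replicate 1 and thus 0 without it, and 1500 over the TRAF2 KO libraries, a ratio of 791 with a counting interval of 219 to 6540. HLA-DQA2, a near copy of HLA-DQA1 and outside the list, had 0 control counts and 1537 TRAF2 KO counts and was at least 541-fold higher. CIITA, the coactivator that switches class II genes on, rose from 26.7 ± 2.9 to 409 ± 12 CPM (chosen after its values were seen).

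Of the 16 measured class II members, 14 rose and 2 fell, and the counts were 14 and 2 adjusted over the list alone. Their median log2 fold change was 4.53, also with the 1 member without control counts (HLA-DRB5) set at its bound. The class II list had camera adjusted p = 7.5e-279, and adjusted p = 1.1e-04 with an estimated correlation. The 2 that fell, LGMN and CTSS, encode lysosomal proteases (chosen after their values were seen). HLA genes have near-identical copies and vary between people, so the split of reads between HLA-DRB1 and HLA-DRB5 and between HLA-DQA1 and HLA-DQA2 is uncertain. RSEM's own sampling put that uncertainty at 0.019% of the count for HLA-DRB1, 3.09% for HLA-DRB5, 0.244% for HLA-DQA1 and 2.01% for HLA-DQA2, not counting any mismatch of the line's alleles to the reference.

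Class I presentation genes moved less. HLA-B rose from 478 ± 11 to 1092 ± 24 CPM, the peptide transporter gene TAP1 from 102 ± 5.9 to 214 ± 4.2 CPM and HLA-F from 14.9 ± 0.8 to 89.1 ± 1.7 CPM, and the 2 HLA values are uncertain where reads are shared with other class I genes. Of 20 measured class I members 11 rose, 3 fell and 6 did not pass. The counts were 12 and 4 adjusted over the list alone. The class I list had camera adjusted p = 1.2e-08, and adjusted p = 0.21 with an estimated correlation. Interferon response genes split. The RNA sensor gene IFIH1 rose from 62.2 ± 2.7 to 123 ± 1.1 CPM, while STAT2 fell from 132 ± 6.0 to 90.7 ± 2.6 CPM. Among the 28 measured interferon genes 9 rose, 12 fell and 7 did not pass (10 and 14 adjusted over the list alone). The interferon list was not called (camera adjusted p = 0.97). Its median (-0.17), mean (-0.11) and camera pointed down, while fry pointed up.

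**Figure D2:**
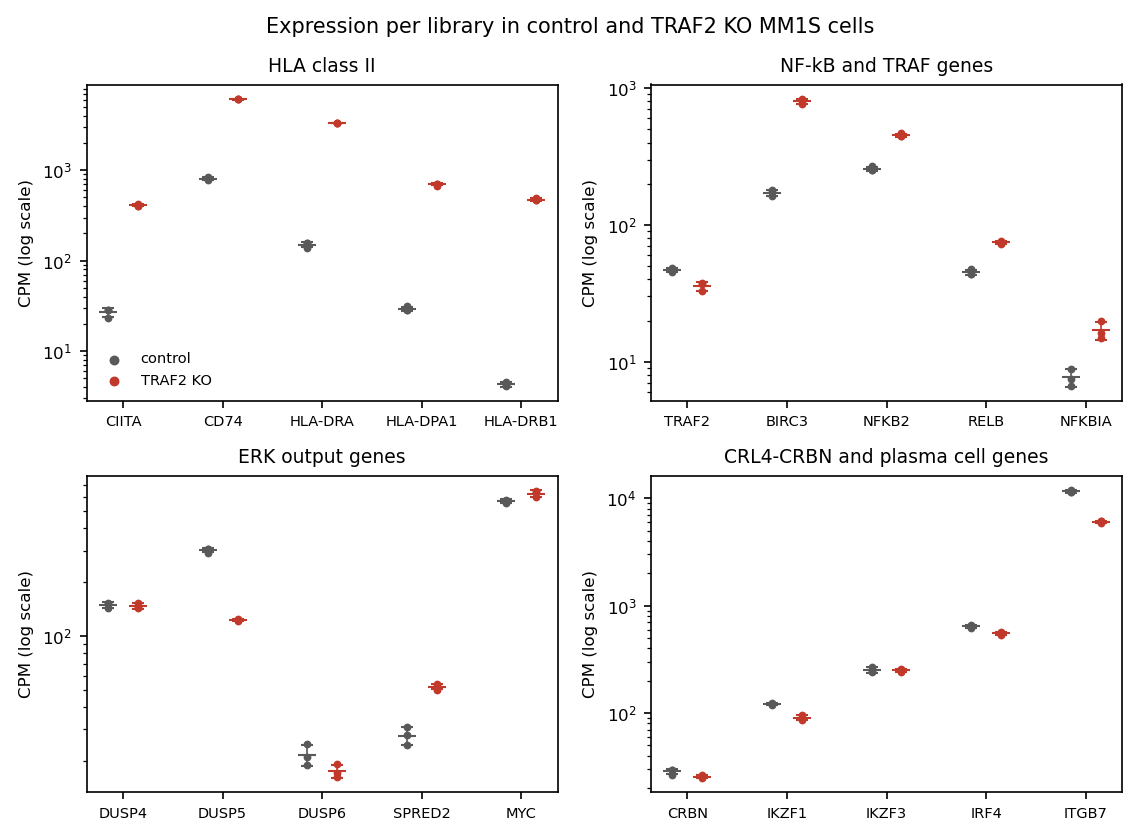
Points are single libraries (3 control in grey, 3 TRAF2 KO in red) and bars the mean ± SD, in CPM on a log scale, for 5 genes in each of 4 groups; CIITA and HLA-DRA were chosen after their values were seen. CD74 sits at 803 CPM in control and 6104 CPM in TRAF2 KO, while DUSP4 and IKZF3 overlap between the genotypes.

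NF-kB genes rose in TRAF2 KO. BIRC3 went from 172 ± 8.0 to 802 ± 32 CPM (log2 fold change 2.22, SE 0.04, edgeR adjusted p = 1.3e-32), and NFKB2, which encodes the precursor of the non-canonical subunit p52, from 257 ± 9.3 to 454 ± 11 CPM. Its partner RELB rose from 45.1 ± 2.0 to 74.4 ± 2.1 CPM, and the feedback inhibitors NFKBIA and TNFAIP3 rose from 7.69 ± 1.10 to 16.99 ± 2.59 and from 309 ± 5.8 to 578 ± 7.8 CPM. All 11 genes of an index of NF-kB activity in myeloma rose (11 adjusted over the list alone), with a median log2 fold change of 1.07. The index had camera adjusted p = 2.6e-54, and adjusted p = 0.0052 with an estimated correlation. PLEK rose by 1.58 on the log2 scale, and CD74 is a member of both this index and the class II list. Of 25 measured NF-kB subunits and common targets, 17 rose, 1 fell and 7 did not pass (17 and 2 adjusted over the list alone). ICAM1, an adhesion gene in that list, rose from 52.0 ± 2.3 to 136 ± 2.7 CPM. The list had camera adjusted p = 8.7e-09, and adjusted p = 0.023 with an estimated correlation. Their median of 0.49 is the same with the 1 member without control counts set at its bound.

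TRAF1 rose from 2.32 ± 0.33 to 37.7 ± 1.1 CPM and TRAF4 from 41.4 ± 0.6 to 116 ± 3.7 CPM. TRAF3 rose by 0.35 on the log2 scale (SE 0.05), BIRC2 fell by 0.42 (SE 0.05), and NIK mRNA (MAP3K14) fell by 0.16 (SE 0.06, edgeR adjusted p = 0.030). Of the 16 members of the TRAF, cIAP and NIK list 8 rose, 4 fell and 4 did not pass (8 and 5 adjusted over the list alone). The TRAF list had camera adjusted p = 4.0e-08, and adjusted p = 0.024 with an estimated correlation. The MAP3K14 call was lost without control replicate 1 (adjusted p = 0.070), control replicate 3 (0.059), TRAF2 KO replicate 2 (0.066) or TRAF2 KO replicate 3 (0.14), with DESeq2 (0.11) and on the TPM scale, in a range of 0.017 to 0.34 over 17 alternatives. The TRAF3 call was lost on the TPM scale (0.29 with a pseudocount of 1, in a range of 6.0e-10 to 0.29). In the TNF families, the death receptor gene FAS rose from 33.3 ± 3.0 to 214 ± 8.2 CPM and CD70 from 36.7 ± 3.2 to 94.7 ± 2.2 CPM. TNFRSF13B (TACI) fell from 152 ± 3.1 to 96.5 ± 0.8 CPM. In that list of 22 measured genes 12 rose, 3 fell and 7 did not pass (12 and 3 adjusted over the list alone). The TNF list had camera adjusted p = 3.7e-06, and adjusted p = 0.039 with an estimated correlation.

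The cytokine gene IL32 rose from 2.59 ± 0.27 to 94.1 ± 0.3 CPM and the interferon-induced chemokine gene CXCL10 from 7.91 ± 0.71 to 34.5 ± 1.4 CPM. IL16 fell from 164 ± 5.1 to 108 ± 2.3 CPM. Of 18 measured cytokine and chemokine genes 5 rose, 3 fell and 10 did not pass (5 and 3 adjusted over the list alone). The cytokine list had camera adjusted p = 0.0096, and adjusted p = 0.12 with an estimated correlation. Adhesion and homing genes went both ways. PECAM1 rose from 6.03 ± 0.66 to 65.7 ± 2.2 CPM, and the integrin gene ITGB7 fell from 11582 ± 252 to 6068 ± 144 CPM. In that list of 25 measured genes 8 rose, 11 fell and 6 did not pass (8 and 11 adjusted over the list alone). It was not called (camera adjusted p = 0.97).

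ERK output genes, which ERK signalling induces and several of which feed back on it, went both ways, with more members higher than lower. DUSP4 was at 149 ± 5.2 CPM in control and 147 ± 5.1 CPM in TRAF2 KO (log2 fold change -0.02, SE 0.04, edgeR adjusted p = 0.81). The phosphatase gene DUSP5 fell from 302 ± 8.7 to 123 ± 1.1 CPM, and DUSP6 fell by 0.30 on the log2 scale (SE 0.10, edgeR adjusted p = 0.017). SPRED2, an inhibitor of the pathway, rose from 27.7 ± 3.2 to 52.0 ± 1.9 CPM, SH2B3 from 34.8 ± 1.0 to 54.0 ± 2.2 CPM and MYC from 569 ± 13 to 627 ± 26 CPM. Over the 13 measured members 7 rose, 3 fell and 3 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.97). Their median log2 fold change was 0.19 and their mean 0.35, but camera did not call the list. SPRY2, SPRY4, EGR1 and FOSL1 lay below the count filter, with 5, 4, 14 and 6 counts over the control libraries and 25, 35, 18 and 3 over the TRAF2 KO libraries. Among these 4, SPRY4 passed edgeR with no filter (adjusted p = 0.0053), and SPRY2 (0.087), EGR1 (0.78) and FOSL1 (0.77) did not. The DUSP6 call was lost without control replicate 2 (log2 fold change -0.19, adjusted p = 0.19), TRAF2 KO replicate 2 (0.064) or TRAF2 KO replicate 3 (0.096) and with DESeq2 (0.092), in a range of 0.0041 to 0.19 over 17 alternatives.

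Immediate early genes also split, with IER5 and JUNB higher (52.7 ± 2.0 to 96.6 ± 2.1 and 27.6 ± 0.7 to 43.7 ± 4.0 CPM) and BTG2 lower (152 ± 1.7 to 96.9 ± 1.2 CPM). Of 19 measured, 6 rose, 4 fell and 9 did not pass (6 and 4 adjusted over the list alone; camera adjusted p = 0.79). Among 24 MAPK pathway components 7 rose, 7 fell and 10 did not pass (8 and 7 adjusted over the list alone; camera adjusted p = 0.97). Their median and mean were above 0 while camera pointed down and fry up. RASA1, which switches RAS off, fell from 191 ± 3.0 to 87.9 ± 4.5 CPM. MAP3K5 rose from 34.7 ± 4.0 to 63.9 ± 3.6 CPM, and RPS6KA3, an ERK-activated kinase gene, rose from 101 ± 3.2 to 134 ± 4.6 CPM.

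CRBN, the target of immunomodulatory drugs, was at 28.6 ± 1.6 CPM in control and 25.6 ± 0.8 CPM in TRAF2 KO (log2 fold change -0.16, SE 0.08), which did not pass (edgeR adjusted p = 0.13). IKZF1, whose protein these drugs direct to degradation, fell from 121 ± 2.1 to 90.8 ± 4.6 CPM, while IKZF3 was at 252 ± 14 and 250 ± 9.5 CPM (edgeR adjusted p = 0.85). CSNK1A1 fell by 0.17 and CUL4B by 0.17 on the log2 scale (SE 0.03 and 0.04). Both calls were lost on the TPM scale (adjusted p = 0.075 and 0.17 with a pseudocount of 1, in ranges of 6.3e-06 to 0.075 and 0.0010 to 0.17). Of 24 genes of the CRL4-CRBN ligase and its drug-induced substrates 3 rose, 5 fell and 16 did not pass (3 and 5 adjusted over the list alone; camera adjusted p = 0.62).

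Among plasma cell identity genes more fell than rose. IRF4, a factor that myeloma cells depend on, went from 644 ± 22 to 553 ± 16 CPM, MAF from 554 ± 12 to 322 ± 3.1 CPM and CD28 from 540 ± 15 to 312 ± 6.1 CPM. Of 23 measured members 16 fell, 3 rose and 4 did not pass (16 and 4 adjusted over the list alone), with a median log2 fold change of -0.28. The plasma cell list had camera adjusted p = 5.9e-09, and adjusted p = 0.10 with an estimated correlation. Of the unfolded protein and integrated stress response genes most fell. ERN1, the sensor IRE1, fell from 348 ± 9.1 to 158 ± 1.6 CPM and EDEM1, which sends misfolded glycoproteins to degradation, from 1284 ± 12 to 631 ± 7.3 CPM. The endoplasmic reticulum chaperone gene HSP90B1 (GRP94) went the other way, from 2549 ± 76 to 4831 ± 29 CPM. Of 30 members 21 fell, 3 rose and 6 did not pass (21 and 3 adjusted over the list alone). The stress response list had camera adjusted p = 2.4e-07, and adjusted p = 0.23 with an estimated correlation.

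Cholesterol synthesis genes included INSIG1 at 385 ± 18 and 845 ± 17 CPM, LSS at 129 ± 3.2 and 210 ± 4.4 CPM and HMGCS1 at 120 ± 6.9 and 178 ± 5.1 CPM in control and TRAF2 KO. Of 24 measured members 16 rose, 0 fell and 8 did not pass (17 and 0 adjusted over the list alone). The cholesterol list had camera adjusted p = 1.2e-05, and adjusted p = 0.24 with an estimated correlation. Among 32 proliferation genes 15 rose, 1 fell and 16 did not pass (17 and 1 adjusted over the list alone). The mitotic checkpoint gene BUB1 rose by 0.46, CDC25A by 0.36 and RRM2 by 0.21 on the log2 scale. That list was near the threshold (camera adjusted p = 0.045, and adjusted p = 0.49 with an estimated correlation). Its call was lost without control replicate 2 (0.055) or TRAF2 KO replicate 1 (0.055), in a range of 2.9e-04 to 0.49 over 16 alternatives. MYC-linked ribosome biogenesis genes moved little, with 13 of 24 higher, 0 lower and 11 not past the test (13 and 0 adjusted over the list alone; camera adjusted p = 0.19). CAD, GNL3 and NOP56 rose by 0.24, 0.21 and 0.16 on the log2 scale. Limma voom called that list (0.0021) and so did the TPM scale (0.029), in a range of 0.0021 to 0.70.

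Glycolysis and hypoxia genes included ENO2 and PFKL, which rose by 0.74 and 0.51 on the log2 scale, and the hypoxia-induced gene ADM, which fell by 0.78. Of 26 measured 13 rose, 6 fell and 7 did not pass (13 and 6 adjusted over the list alone; camera adjusted p = 0.29). The list was called with limma voom (0.023) and on the TPM scale (0.025), in a range of 0.023 to 0.87. Of 24 measured p53 targets 9 rose, 4 fell and 11 did not pass (9 and 5 adjusted over the list alone; camera adjusted p = 0.34). PLK2 fell from 49.99 ± 1.89 to 12.05 ± 0.96 CPM and SESN1 from 130 ± 4.0 to 75.8 ± 1.6 CPM, while FAS rose. Of 26 measured apoptosis regulators 7 rose, 11 fell and 8 did not pass (8 and 12 adjusted over the list alone; camera adjusted p = 0.62). Their median was -0.09 and their mean -0.03, while camera and fry pointed up. The caspase-8 inhibitor gene CFLAR rose from 89.8 ± 5.4 to 175 ± 2.5 CPM and CASP10 fell from 152 ± 4.0 to 118 ± 3.7 CPM.

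Markers of other cell types were mostly below the filter. Among B cell markers, BACH2 fell from 21.7 ± 2.3 to 7.61 ± 0.41 CPM and CD79B from 38.9 ± 3.0 to 20.2 ± 0.5 CPM, while SPIB rose from 0.141 ± 0.131 (8 counts) to 2.20 ± 0.94 CPM. Of 15 such markers 5 were measured, and 1 rose, 3 fell and 1 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.11). Of 3 measured myeloid markers, CD68 fell from 34.8 ± 2.5 to 9.91 ± 1.56 CPM, ITGAM rose from 0.992 ± 0.344 to 5.06 ± 0.84 CPM and FCER1G did not pass. The counts were 1 and 1 adjusted over the list alone (camera adjusted p = 0.44). The median and mean were above 0 while camera and fry pointed down. Of 2 measured T and NK cell markers CD3E rose from 1.99 ± 0.21 to 3.96 ± 0.54 CPM and CD2 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.83). The 2 measured erythroid markers, HBB and HBD, did not pass edgeR either (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05; camera adjusted p = 0.83). Of 7 measured stromal markers 5 rose and 2 did not pass (5 and 0 adjusted over the list alone). The stromal list had camera adjusted p = 0.0015, and adjusted p = 0.10 with an estimated correlation. Among the 5 were the matrix genes COL1A1, which rose from 0.212 ± 0.093 to 7.79 ± 0.55 CPM, COL6A1, from 0.209 ± 0.154 to 5.46 ± 0.51 CPM, and SPARC, from 14.4 ± 1.1 to 31.0 ± 0.8 CPM.

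None of the 13 mitochondrially encoded mRNAs passed edgeR (0 adjusted over the list alone), with log2 fold changes of -0.19, -0.21 and -0.08 for MT-CO1, MT-CO2 and MT-CO3. Of the 13, 0 had an unadjusted edgeR p under 0.05, and DESeq2 and limma voom did not call these 3 genes, but each was called as lower in 3 of 17 alternatives, with adjusted p ranging from 2.7e-08 to 0.41, 2.8e-10 to 0.33 and 0.0024 to 0.64. Without control replicate 1 MT-CO1 (log2 fold change -0.27, adjusted p = 2.0e-05) and MT-CO3 (-0.13, 0.0024) were called, and without TRAF2 KO replicate 2 MT-CO2 (-0.26, 0.036). Non-robust dispersions called MT-CO1 (0.0069) and MT-CO2 (0.0032), and no count filter MT-CO3 (0.034). That list was not called (camera adjusted p = 0.50), but it was called as lower without control replicate 1 (0.0018) and with limma voom (0.023), in a range of 0.0018 to 0.91. Of 12 measured replication-dependent histone genes, whose mRNAs lack poly(A) tails, H1-2 rose by 0.32 on the log2 scale and 11 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.62). H2AC20 had a log2 fold change of -0.64 (SE 0.26) and H2AC6 of 0.65 (SE 0.28), and leaving out control replicate 2 called both (-0.76 and 0.89, adjusted p = 0.040 and 0.027). Leaving out TRAF2 KO replicate 3 (-0.93, adjusted p = 0.018) or upper quartile scaling (0.049) called H2AC20, and the ranges were 0.018 to 0.26 and 0.027 to 0.23. The TPM scale called that list (adjusted p = 0.029, in a range of 0.029 to 0.87).

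Outside the lists, LRRC4B rose from 0.070 ± 0.121 (4 counts, all in control replicate 2) to 13.5 ± 0.6 CPM and RFTN1, which encodes a lipid raft protein of B cells, from 1.42 ± 0.25 to 108 ± 5.4 CPM. The 7 largest falls by the naming rule were those of MYO7A, DDIT4L, GRHL3, HAVCR2, CD300A, PLXND1 and CSGALNACT1, with log2 fold changes of -3.12, -3.11, -2.89, -2.85, -2.81, -2.66 and -2.59. HAVCR2, which encodes the immune receptor TIM-3, fell from 36.0 ± 0.8 to 5.005 ± 0.971 CPM, the plexin gene PLXND1 from 69.1 ± 1.4 to 10.9 ± 1.2 CPM and the epithelial transcription factor gene GRHL3 from 36.0 ± 1.5 to 4.86 ± 0.78 CPM.

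**Figure D3:**
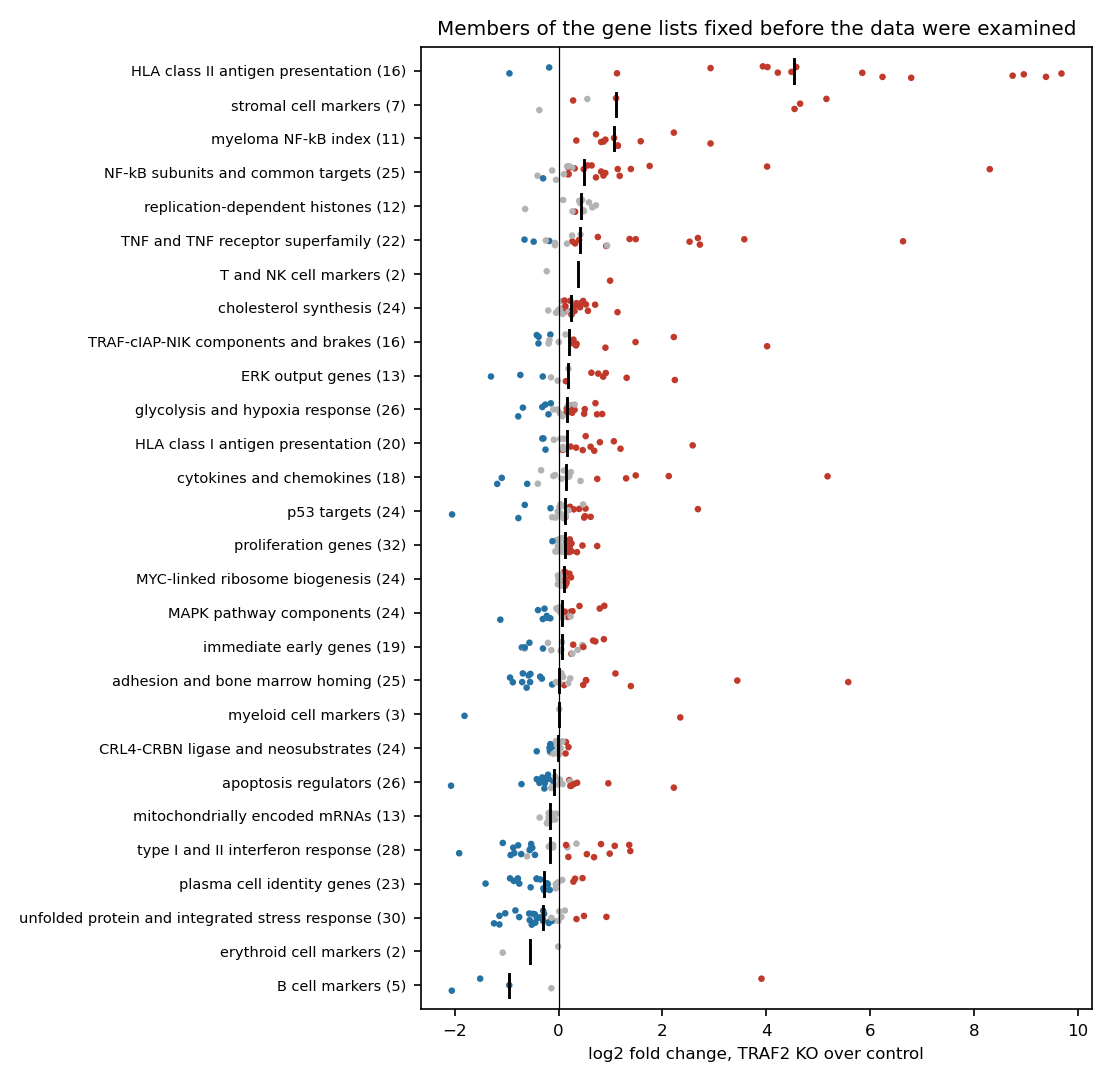
Each point is a measured member of a list (number measured in brackets) at its log2 fold change of TRAF2 KO over control; red and blue points passed the edgeR test as higher or lower, grey points did not, and black bars are list medians. The class II median of 4.53 stands apart from the others, while the interferon, MAPK and adhesion lists hold members on both sides of 0.

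Of the 28 lists, camera with the preset correlation called 12, 10 up and 2 down. With an estimated correlation 5 held: class II, the myeloma NF-kB index, NF-kB subunits and targets, the TRAF, cIAP and NIK genes, and the TNF families. Several of these lists share members, so the 5 calls are not separate results. NFKB2, RELB and NFKBIA are in the index and the NF-kB list. BIRC3 and TNFAIP3 are in the index and the TRAF list, and TRAF1 is in the TRAF and NF-kB lists. Regroupings of the 6 libraries that mix the genotypes gave 4 to 10 lists called with the preset correlation and 0 with the estimated one. Each such regrouping leaves part of the genotype difference between its groups and puts the rest within them. Neither count is therefore a chance level for the 12 or the 5 calls. The 7 lists not called with an estimated correlation are described here by their members' own tests.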

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

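All settings here were planned before the data were examined. Over 17 alternatives the count of changed genes ran from 2747 to 5092 against 4863, and 0 of 1731 values of the 102 named genes tested turned direction with a call: 1700 kept their direction and call, 17 lost the call and 14 gained one. On the TPM scale with a pseudocount of 1, limma called 2747 genes (1339 higher, 1408 lower), 417 of them at least 2-fold (269 higher, 148 lower), and with 0.1 it called 2771 (1352 higher, 1419 lower), 713 of them at least 2-fold (446 higher, 267 lower); 54.1% and 54.5% of the edgeR calls were called there with the same sign, and 75.2% with DESeq2, which called 3765. The cause was not tested. Leaving out 1 library gave 4188 to 4544 changed genes and 830 to 880 changed at least 2-fold. Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at 0.0065 to 0.048, and those of differently numbered ones of the other genotype at -0.049 to 0.026. These ranges overlap. Of 6 libraries 4 correlated best with their own number, which is at most a weak hint, since the 6 matches depend on each other. Mitochondrial genes took 1.69%, 2.10% and 2.01% of the counts in control replicates 1, 2 and 3. In TRAF2 KO replicates 1, 2 and 3 they took 1.65%, 1.83% and 1.73%, the same order, which 3 libraries per group can share by chance. With the number as a replicate block 5092 genes were called, MT-CO1 (adjusted p = 2.7e-08), MT-CO2 (2.8e-10), MT-CO3 (0.017) and H2AC20 (0.047) among them. Of 448 list results 427 kept their call and direction, 14 lost it, 7 gained one and 0 reversed. An estimated correlation ended the calls of plasma cell identity (adjusted p = 0.10), class I (0.21), cytokines (0.12), proliferation (0.49), stress response (0.23), cholesterol (0.24) and stromal lists (0.10). Cytokines lost the call with limma voom (0.27) and on the TPM scale (0.15). Proliferation lost it with upper quartile (0.066) or library-total scaling (0.056) and the filter of 1 CPM (0.058), and ran from 0.018 to 0.055 with 1 library left out. Calls were gained with limma voom by the MYC-linked (0.0021), glycolysis (0.023) and mitochondrial lists (0.023), and on the TPM scale by the MYC-linked (0.029), glycolysis (0.025) and histone lists (0.029); the mitochondrial list ran from 0.0018 to 0.72 with 1 library left out. The cause was not tested. In the simulation 2-fold changes were recovered in 86% of genes and smaller ones less often. It changed far fewer genes than the 4863 called here, so its adjustment was stricter and its shares need not hold for these data.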

Other observations

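The lists and the transcript length comparison in this part, both tests of the class II rise, the comparison of chromosome 19 with the others, and the count of lists with an estimated correlation over splits were chosen only after the results were seen. Among lysosomal genes CTSB, a cathepsin, went from 291 ± 10 (SD, n = 3) to 131 ± 1.9 CPM (SD, n = 3) and PSAP, the precursor of the saposins, from 1527 ± 50 to 878 ± 17 CPM, while CTSH rose from 2.57 ± 0.21 to 17.3 ± 1.9 CPM. Of 33 lysosomal genes 21 fell, 4 rose and 8 did not pass. Of genes linked to MAF in myeloma most fell, with DEPTOR, an inhibitor of mTOR, at 304 ± 13 and 142 ± 3.8 CPM and TLR4 at 51.6 ± 0.8 and 8.69 ± 1.41 CPM, although CCND2 rose from 649 ± 3.5 to 894 ± 25 CPM. Of 13 measured, 10 fell and 3 rose, and MAF, ITGB7 and CCND2 are also in the plasma cell list.

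Ligands and receptors of T cell costimulation and inhibition moved in both directions. ICOSLG rose from 43.2 ± 1.3 to 153 ± 8.4 CPM, TNFSF9 (4-1BB ligand) from 8.41 ± 2.13 to 55.4 ± 2.4 CPM and CD274 (PD-L1) from 2.22 ± 0.24 to 6.02 ± 1.08 CPM, while VSIR (VISTA) fell from 12.5 ± 0.4 to 3.25 ± 0.60 CPM. Of 20 measured 10 rose, 6 fell and 4 did not pass. Among 13 factors that act at class II promoters 2 rose, 1 fell and 10 did not pass, with a median log2 fold change of 0.03. The 2 were CIITA and RFX5, which rose from 109 ± 2.2 to 255 ± 6.7 CPM, and CIITA is also in the class II list. Camera was run on these 4 lists, but each holds genes seen before it was made, so its p-values are not given.

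Had antigen-presenting cells brought the class II rise, they would make up at least 1.10% of the RNA, and at that share the highest of 8 abundant B cell and myeloid markers, S100A9, would be at 28.9 CPM within them (upper counting limit 46.3), against a median of 25.1 CPM over the tested genes. Over the TRAF2 KO libraries MS4A1 had 5 counts, CD79A 8, LYZ 2 and TYROBP 1, and with control counts taken off S100A9 would be at 16.1 CPM (upper limit 32.5, above that median). The listed B cell markers changed by -32.3 CPM and the myeloid by -20.5 CPM in total, with BACH2, CD79B and CD68 lower from levels that would hide a small share, while ITGAM and SPIB rose, so a contribution of such cells stays open. Had shared reads alone brought the class II rise, genes without a near copy would have stayed in place. The smaller log2 fold change of CIITA and CD74 was 2.93, a value known when this test was set. It does not test how reads split between near copies such as HLA-DQA1 and HLA-DQA2. A response to loss of TRAF2 and a divergence of the 2 populations apart from TRAF2 both stay open and untested, since each genotype has 1 guide.

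The count of changed genes was weighed against chance and copy number. Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many changed genes (4863, highest other 0), as many changed at least 2-fold (855, highest other 0), as many called lists (12, highest other 10) and as many lists with an estimated correlation (5, highest other 0), and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 edgeR gave 137 to 219 genes in the other splits and 5809 in the real one. No other tool was run on the splits. Each other split mixes the genotypes within its groups, so the genotype difference widens the spread there. Its low counts follow from this and are no chance level, so the splits cannot weigh chance. A copy number difference would shift runs of neighbouring genes, but windows of 50 neighbouring genes beyond the range of random order held 1.83% of the changed genes and 1.51% of all ordered genes (4 of 265 windows, 3 on chromosome 19 and 1 on chromosome 6, with 0.265 expected). Of 18 windows on chromosome 19, 17 had medians above 0. Its 883 tested genes had a median log2 fold change of 0.0785, against -0.0261 to 0.0233 on the other chromosomes. On it 227 genes were called higher and 90 lower. It held 6.53% of the changed genes and 883 of the 13272 tested genes matched to the reference order, a share no lower. A copy number difference of chromosome 19 may remain, and other sources of so small a shift were not tested.

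TRAF2 mRNA was weighed against loss of the chromosome end beyond the gene, which cutting by the guide could cause. The 27 tested genes beyond TRAF2 on chromosome 9 had a median log2 fold change of 0.078 (bootstrap SE 0.073), and the 50 genes before it 0.079, which argues against loss of the end in most cells. Decay of an edited transcript was not tested. Transcript length, compared between genotypes with limma in 8975 genes with at least 100 counts, differed in 0 genes after adjustment, with robust variances or without. At an unadjusted p under 0.05 there were 551 genes, where 449 are expected by chance, and the smallest adjusted p was 0.082. TRAF2's own length was 2143, 2166 and 2116 in the control libraries and 2171, 2192 and 2223 in the TRAF2 KO libraries. These groups did not overlap, as in 1021 of the genes, where 897.5 are expected by chance, and TRAF2 did not pass after adjustment.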
